A study of Arabidopsis thaliana with 2 samples.

How the data were processed

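Protoplasts, which are plant cells freed from their walls, were prepared from mesophyll tissue, the photosynthetic ground tissue of the leaf, of Arabidopsis thaliana. Per the labels' protocols, the fifth and sixth leaves of 36 plants were harvested 2 h after the onset of light, and the pooled cells were divided into a control sample and a hypoxia sample. Control cells stood for 6 h in 10 ml of mannitol buffer in a dish 150 mm wide, at a depth of 0.6 mm. Hypoxic cells stood for 6 h in 2 ml of the same buffer in a 15 ml tube, at a depth of 25 mm. The number of cells was equal, and both stood in light of 80 microeinstein. Total RNA was purified and 8 micrograms of it were labelled with biotin by T7 transcription for an Affymetrix expression array, per the labels' protocols.

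The deposited values were probe set intensities on a linear scale, with 1 column per array. GCOS 1.0 was named per the submitters' processing notes. Its settings and the genome build behind the probe sets were not given in the sources used here. From the values, the authors had scaled each array as a whole: the mean of a column without its lowest and highest 2% of probe sets was 1500.1 on both arrays. No detection calls or spot-level background values were used here, so whether a probe set was above background was judged by a floor alone.

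Each array carried 22810 probe sets, of which 64 were manufacturer's controls and were left out of all gene results. A table from an older platform annotation paired 13513 of the other 22746 probe sets with 1 gene and 503 with several genes, and 8730 have no gene name here. Symbols were updated through the Entrez identifiers in a RefSeq gene table of the assembly TAIR10.1, which matched 13436 of the single-gene probe sets. Only single-gene probe sets entered the gene results, which gave 13355 genes. No coordinates are printed, since the build used for the array was not given. ADH1 and PDC1, the marker genes named by the series design, were not analysed here.

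Each array was divided by its median over the probe sets other than controls and multiplied by the geometric mean of both medians. The floor was the 40th percentile of the pooled scaled values, an intensity of 165.7, and lower values were set to it. The log2 ratio of hypoxia over control was then taken. For a gene with several probe sets, the probe set with the highest mean log2 intensity was used. A gene counted as measured when it lay above the floor on at least 1 array. A ratio with 1 array at the floor is a lower bound on the change and is given as such. Intensities are printed as deposited, and ratios are from the scaled values.

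With 1 array per group no test across genes was possible, so counts of genes that differed at least 2-fold are descriptions of these 2 arrays. For each list with at least 3 measured members, the median log2 ratio was set beside 10000 random lists of the same size, matched on mean log2 intensity in 20 bins. The share of random lists with a lower median, given as a percentile, describes these arrays only. Probe noise was measured from genes with 2 probe sets above the floor on both arrays.

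Before the data were examined, 23 gene lists were fixed. They covered the core hypoxia response, fermentation and sucrose cleavage, cytosolic glycolysis, genes induced by KIN10 and sugar starvation, branched-chain amino acid breakdown, ATG8 autophagy genes, the trehalose phosphate synthase family, nuclear photosynthesis genes, heat shock proteins and chaperones, and touch and wounding genes. Others covered the mitochondrial retrograde response, ethylene, cell wall loosening, the circadian clock, nitrogen assimilation, anthocyanin synthesis, markers of guard cells, phloem and epidermis, reference genes, cytosolic ribosomal proteins, plastid-encoded genes and mitochondria-encoded genes. Of these, 20 were given by locus and the last 3 by a pattern in the symbol or locus. The pattern for plastid genes was replaced, after the gene table was seen, by that table's plastid chromosome, because the table writes those loci with another prefix. The patterns for cytosolic ribosomal proteins and for mitochondria-encoded genes matched 0 genes. After the data had been seen, 6 lists were added: ribosome biogenesis factors, cytosolic ribosomal proteins by locus, endoplasmic reticulum folding, proteasome subunits, other chaperones and mitochondria-encoded genes by symbol.

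The genes named in the text followed a rule fixed before the data were examined. It took ADH1 and PDC1, the 15 highest and 15 lowest ratios among genes above the floor on both arrays, and the 5 strongest bounds in each direction among genes at the floor on 1 array. It also took the up to 4 members with the largest absolute ratio in each list, and every member of lists of 10 or fewer. A gene that this rule takes is not reported here. Other members named beside them, and all members of the 6 added lists, were chosen after their values were seen.

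Alternatives changed 1 choice at a time: values as deposited, quantile normalization, intensity-dependent loess with a span of 0.4, centring on the reference genes, floors at the 20th and 60th percentile, 16 added in place of a floor, the mean over a gene's probe sets, and gene-specific probe sets. Counts were also taken at 1.5-fold and 3-fold and with both arrays above the floor, and random lists were drawn with 10 bins and with no matching. Centring on the hybridisation controls, counting all probe sets, and the plastid list without its 10 highest members were added after the data had been seen.

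The steps were tested on simulated data for the comparison of hypoxia with control, with 7551 genes and noise with an SD of 0.3 log2. Of simulated genes with a log2 ratio of 2, 100% were called at least 2-fold, and of those at -2, 98.0%. At a true log2 ratio of 1 or -1, which lies at the threshold, 34.0% and 46.9% were called. Of the unchanged genes, 1.4% were called. The simulation held no variation between samples beyond this noise, so 1.4% is not the false-call rate of the real arrays. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.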

Results

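Transcript levels of Arabidopsis mesophyll protoplasts were measured on 1 array after 6 h under hypoxia, produced by submerging the cells 25 mm deep in buffer, and on 1 array after 6 h in a shallow layer of 0.6 mm. The median intensity was 345 on the control array and 334 on the hypoxia array, and 57.8% and 62.2% of the probe sets lay above the floor. Of 13355 genes, 7972 were measured on at least 1 array and 5383 lay under the floor on both. The number of arrays limits the precision, and no difference given here has a replicate check. The series asked which genes hypoxia induces in these cells, and how far they overlap with genes induced by KIN10, a catalytic subunit of the SnRK1 kinase that acts when cellular energy is low.

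Genes of the core hypoxia response and small heat shock genes were among the highest ratios of hypoxia over control. The highest among genes above the floor on both arrays was AT1G54050, a small heat shock gene, whose intensity was 274 in control and 26057.5 in hypoxia, a log2 ratio of 6.62. HUP32, HUP54 and HUP26, which belong to a set of hypoxia-responsive genes of unknown function, followed at 6.08, 5.95 and 5.36. At the other end, AT2G39710, an aspartyl protease gene, went from 4876 to 377, a log2 ratio of -3.65.

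At least 2-fold higher in hypoxia were 1037 genes, 13.0% of those measured, and at least 2-fold lower were 1156, or 14.5%. The other 5779 lay within 2-fold. Differences of at least 8-fold were counted for 44 higher and 11 lower genes. The balance of the 2 directions depended on the scaling and on the floor: 47.3% of the genes past 2-fold were higher in the main setting, 85.4% when the arrays were centred on the reference genes, 17.7% when they were centred on the hybridisation controls, and 61.8% with the floor at the 20th percentile. Both centrings moved the median of all measured genes by 0.47 and -0.48 on the log2 scale, so directions of modest size are relative to the other genes on the array.

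**Figure D1:**
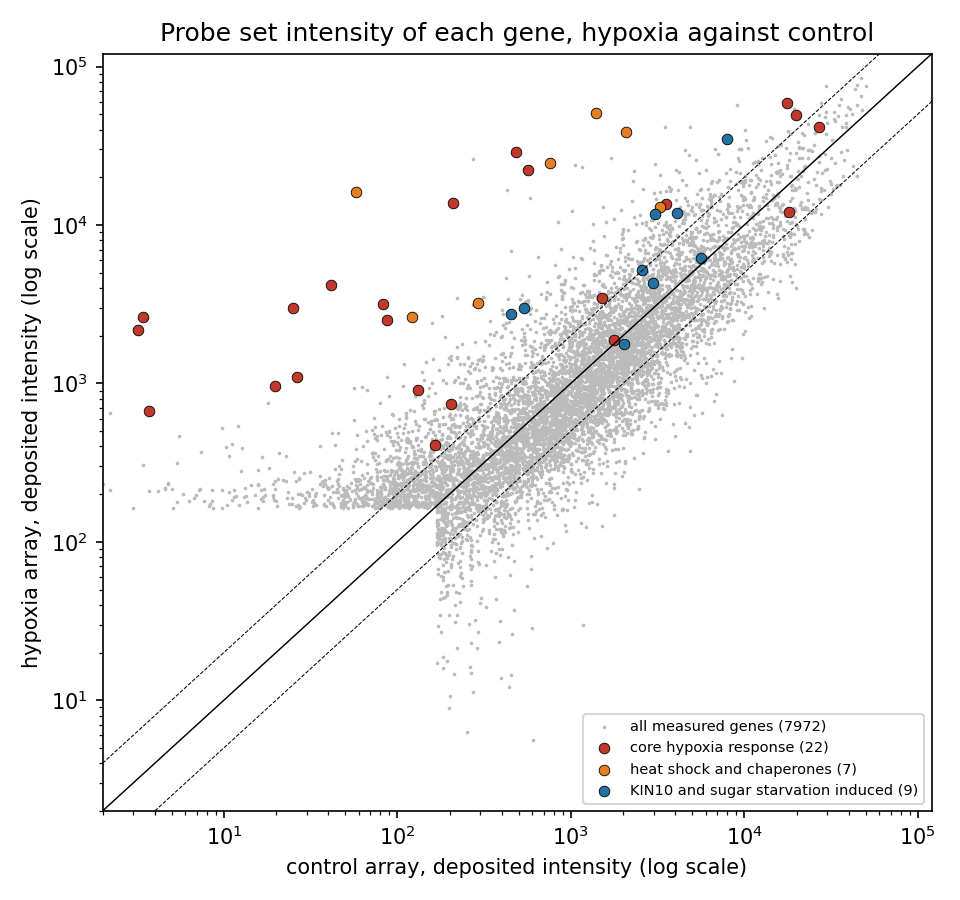
Deposited intensity of each of the 7972 measured genes on the hypoxia array (vertical, log scale) against the control array (horizontal, log scale), with 3 gene lists in colour; the solid line marks equal intensity and the dashed lines 2-fold differences. Most members of the core hypoxia and heat shock lists lie far above the upper dashed line, and 11 core hypoxia genes were at the floor in control.

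The core hypoxia response, a list of genes that low oxygen induces across plant tissues, was higher for almost all genes measured. Of its 51 listed genes, 22 were measured. Of these, 19 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.52, which is 5.73-fold. HUP32 went from 209.5 to 13712, HUP54 from 485 to 29012 and HUP26 from 564 to 22394. In control, 11 members were at the floor. Among these, AT4G33560 was at least 25.7-fold higher, AT2G17850 at least 19.5-fold, AT3G29970 at least 18.3-fold, WIP4 at least 16.1-fold, and HRU1, a universal stress protein gene, at least 15.5-fold. HRA1, a transcription factor gene that restrains the hypoxia response, was at least 6.74-fold higher. CML38, which encodes a calmodulin-like protein, went from 3558 to 13528, a log2 ratio of 1.97. Within 2-fold were AT5G27760 at 0.68, HUP40 at 0.12 and PDC2, a pyruvate decarboxylase gene, at -0.53. The median lay above those of all 10000 random lists, whose central range was -0.58 to 0.41. Because so many members were at the floor, the median was a bound that moved with it, to 1.71 with the floor at the 60th percentile and 3.36 at the 20th. At least 2-fold higher were 13 of 21 measured members with the floor at the 60th percentile and 20 of 24 at the 20th. With reference gene centring 20 of 23 were, and with hybridisation control centring 16 of 22, where 1 was at least 2-fold lower. ADH1 and PDC1, which the study itself read on these samples as its check of the treatment, were not analysed here.

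Fermentation and sucrose cleavage, with 3 measured members, had a median of 0.02 at percentile 53.1. PPDK, which encodes pyruvate orthophosphate dikinase, was 3.02-fold higher, from 4079 to 11928. LDH1, a lactate dehydrogenase gene, had a ratio of 0.02, and PDC2 went from 18046 to 12106. Cytosolic glycolysis, with 5 measured members, had a median of -0.01 at percentile 46.2, with 0 members at least 2-fold higher and 1 at least 2-fold lower, AT5G08570, which came within 2-fold with quantile normalization, loess and reference gene centring. With reference gene centring 1 member was at least 2-fold higher, GAPC2. Its members were the pyruvate kinase genes AT5G08570, AT5G63680 and AT5G56350 at -1.02, -0.40 and 0.13, the glyceraldehyde phosphate dehydrogenase gene GAPC2 at 0.55 and the triose phosphate isomerase gene TPI at -0.01. Both medians were above 0 with reference gene centring and below 0 with hybridisation control centring and with values as deposited. Since 17 and 21 genes stood in these lists, most of each pathway was not analysed here.

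Genes induced by KIN10 and sugar starvation were higher as a group. Of 36 listed genes, 9 were measured. Of these 9, 6 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.59, or 3.02-fold. MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, went from 453 to 2748, a ratio of 2.65. ETFQO, which passes electrons from amino acid breakdown to ubiquinone, had a ratio of 2.53. SEN5, a senescence-associated gene, went from 7998 to 35067, a ratio of 2.18, and ATG8E, an autophagy gene, from 3044 to 11729, a ratio of 1.99. AKINBETA1, a regulatory subunit gene of SnRK1, was 2.09-fold higher, while IVD, CCL and D2HGDH had ratios of 0.59, 0.18 and -0.15. The median lay above all 10000 random lists. With hybridisation control centring 5 members were at least 2-fold higher, and with reference gene centring 7 were. The list was drawn up from what is known of KIN10 targets, and the series design already reports this overlap in these cells, so the list is not independent evidence of its direction. It shared 0 measured members with the core hypoxia list.

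The enzymes of branched-chain amino acid breakdown lay on both sides of 0. Of 10 measured members, 2 were at least 2-fold higher, MCCA and ETFQO, which the KIN10 list also holds, and 0 were at least 2-fold lower. ETFA was at -0.71. Among further members, ETFB was at 0.39, BCKDHA2 at -0.44, MCCB at -0.25 and ALDH6B2 at 0.13. The median was 0.26 at percentile 87.5, and it went to -0.24 with hybridisation control centring. With reference gene centring, 5 members were at least 2-fold higher. All 9 ATG8 genes, whose products are attached to autophagosome membranes, were measured. ATG8E and ATG8H were at least 2-fold higher, at 1.99 and 1.59, and ATG8G was at least 2-fold lower, at -1.004, though within 2-fold under 5 alternatives. ATG8F, ATG8I, ATG8A and ATG8C lay at 0.70, 0.56, 0.47 and 0.27, and ATG8B and ATG8D at -0.01 and -0.43. Their median was 0.47 at percentile 88.3, and it went to -0.035 with hybridisation control centring, while 5 ATG8 genes were at least 2-fold higher with reference gene centring.

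The measured heat shock and chaperone genes were all higher. In the main setting their median was the largest of the 11 fixed lists for which one was computed. With 16 added in place of a floor the order was the other way round, at 4.71 for the core hypoxia list and 4.297 for this one. Of 24 listed genes, 7 were measured. All 7 were at least 2-fold higher, and the median log2 ratio was 4.25, or 19.0-fold, above all 10000 random lists. HSP26.5 was at the floor in control and at least 98.9-fold higher, reaching 16113. HSP17.6C went from 1394 to 50596, FKBP65, a peptidyl-prolyl isomerase gene, from 758 to 24783, and HSP17.6B from 2086 to 38354. HSP22 was at least 16.1-fold higher, HSP15.7 11.4-fold, and HSP23.5, a mitochondrial small heat shock gene, 4.07-fold. Among the 15 highest ratios of genes above the floor on both arrays, 3 genes were from this list and 3 from the core hypoxia list. Outside both lists were AT1G71000 at 5.33 and AT2G20560 at 4.55, which encode DnaJ-type co-chaperones, and Hop3, which links the HSP70 and HSP90 chaperones, at 4.38. Further genes of the 15 were AT2G47950 at 4.70, ZCF37 at 4.02, the RING finger gene AT1G14200 at 4.02, AT2G20670 at 3.98 and AT2G21630 at 3.92.

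Plastid-encoded transcripts were higher by a modest amount, and broadly. Of 69 measured genes, 31 were at least 2-fold higher, 0 at least 2-fold lower, and 67 had a ratio above 0. At least 2-fold higher were 13 genes with hybridisation control centring, where 2 were at least 2-fold lower, and 64 with reference gene centring. The median log2 ratio was 0.80, or 1.74-fold, above all 10000 random lists, and 0.29 with hybridisation control centring. The ribosomal protein genes rps15, rpl20, rpl33 and rps18 had the highest ratios, at 2.56, 2.40, 2.05 and 2.00. The 2 genes below 0 were psaJ at -0.64 and psbA, which encodes the D1 protein of photosystem II, at -0.63. Nuclear photosynthesis genes were measured for 7 of 40 listed. Of these, 4 were at least 2-fold higher and 0 at least 2-fold lower: PSAN, a photosystem I subunit, at 1.42, the Calvin cycle enzyme genes PRK and SBPASE at 1.41 and 1.37, and the antenna gene LHCB4.2 at 1.04. LHCB4.1, RCA and LHCB4.3 lay at 0.88, 0.75 and 0.40. Their median of 1.04 stood at percentile 97.4, just inside the central range of random lists, which ended at 1.05, and it lay above that range under 9 of 12 alternatives. The 9 include both centrings, at 97.69 and 98.16, which could hardly change a percentile. All alternatives reuse the same 2 arrays, so the 9 add no support and the list stays borderline. All 4 genes past 2-fold came within 2-fold with hybridisation control centring.

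**Figure D2:**
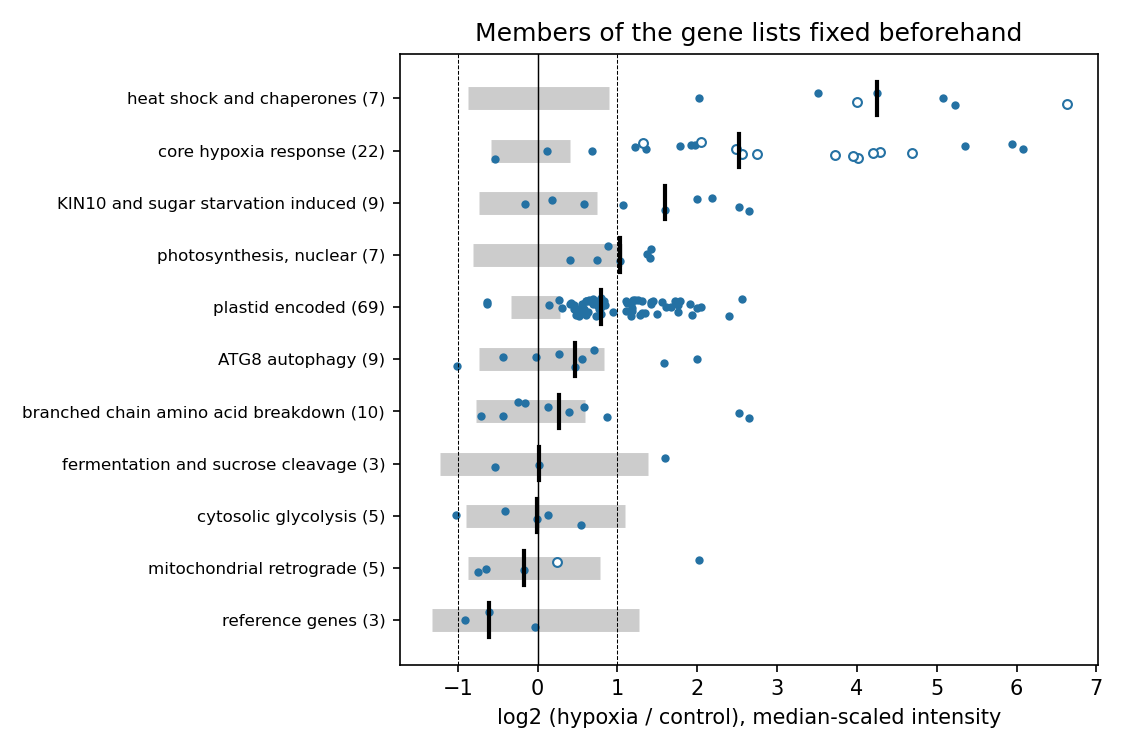
Log2 ratio of hypoxia over control (horizontal) for each measured member of the 11 fixed lists with at least 3 measured members, whose number stands in brackets; open points had 1 array at the floor, black bars are medians, grey bands hold the central range of medians of 10000 random lists, and dashed lines mark 2-fold. The heat shock, core hypoxia, KIN10 and plastid medians lie beyond their bands, at 4.25, 2.52, 1.59 and 0.80; the ATG8, branched-chain and fermentation medians turn negative with hybridisation control centring (fermentation also with values as deposited), the glycolysis and mitochondrial retrograde medians turn positive with reference gene centring, and the latter also with the floor at the 20th percentile.

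The lowest ratios among genes above the floor on both arrays belonged to genes of varied function. After AT2G39710 came AT5G21105, an ascorbate oxidase gene, at -3.51, AT2G34357 at -3.47, the serine carboxypeptidase gene AT5G22860 at -3.24, the sugar transporter gene AT3G05400 at -3.13 and NANA, an aspartyl protease gene, at -3.10. AT3G57010 and AT3G61930 both had -3.06. The ribosomal protein gene AT5G39850 went from 8681 to 1037, a ratio of -3.02, and RRP41L, related to a subunit of the RNA exosome, had -2.99. AT4G37295 had -2.98, the chitinase gene ChiC -2.97, the pectin methylesterase gene AT3G43270 -2.96, AT5G60630 -2.95 and AT2G34050 -2.89. At the floor in hypoxia were PPR596, a pentatricopeptide repeat gene, at least 10.5-fold lower, the methyltransferase gene BSMT1, at least 8.94-fold lower, the pectin methylesterase gene ATPMEPCRB, at least 7.23-fold lower, and AT5G02580 and AT3G61100, at least 7.03-fold and 6.85-fold lower. The last 3 of these came within 2-fold with the floor at the 60th percentile.

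Other stress and signalling lists held few measured members. In the mitochondrial retrograde list, 1 of 5 was at least 2-fold higher, HSP23.5, and NDB2, UPOX and GSTU25 had ratios of -0.75, -0.64 and -0.17. AT12CYS-2 was at the floor in control, with a ratio of at least 0.25. The median was -0.17 at percentile 38.7, and it was above 0 with reference gene centring and with the floor at the 20th percentile. Of the touch and wounding genes, WRKY53 was at -0.91 and ZAT10 at 0.41. The ethylene signalling gene EIN3 was at 0.77, and the clock gene GI at -0.60. The expansin gene EXPA8 and the anthocyanin gene DFR were at the floor in control, with ratios of at least 0.93 and 0.67. The trehalose phosphate synthase, nitrogen assimilation and epidermis lists had 0 members with a single-gene probe set. Their genes were therefore not analysed here, which says nothing about their expression.

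Markers of other leaf cell types were measured for guard cells and phloem. The guard cell gene FAMA had a ratio of 0.20, with an intensity of at most 328. GC1 was at the floor in control and reached 175 in hypoxia, just above the floor, so its ratio of at least 0.11 is a bound. The phloem gene SWEET11 went from 212 to 1020, a ratio of 2.31, which fell to 0.62 with the floor at the 60th percentile. Among the 3 measured reference genes, SAND was at -0.91, TIP41 at -0.61 and UBC21 at -0.03, with a median of -0.61 at percentile 21.8.

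Signs of RNA quality were close between the arrays. The 3′ over 5′ intensity ratio was 1.33 in control and 1.39 in hypoxia for actin, 0.954 and 0.951 for glyceraldehyde phosphate dehydrogenase, and 1.42 and 1.39 for ubiquitin. Another set of control probe sets for the same genes gave 4.96 and 4.48 for actin, 0.824 and 0.974 for glyceraldehyde phosphate dehydrogenase, and 2.18 and 1.92 for ubiquitin. In 74 genes with 2 probe sets above the floor on both arrays, log2 ratios had a probe set SD of 0.35, and 54 pairs had the same sign. All 18 hybridisation control probe sets were higher on the hypoxia array, with a median log2 ratio of 0.50 and a range of 0.06 to 0.80.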

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

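The tests weighed here for heat shock genes and plastid transcripts were chosen after the results had been seen. For ribosome assembly genes, the tests by background list and by scaling were written before their results were seen, and the test of RNA degradation after.

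The probe set for 5S ribosomal RNA, a manufacturer's control that entered no comparison, had an intensity of 260.0 in control and 3085 in hypoxia, a 12.3-fold difference. The probe set for 25S ribosomal RNA lay under the floor on both arrays, at 107 or less.

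Probe sets without a single gene name also entered no comparison. Of 6680 measured ones, 981 were at least 2-fold higher in hypoxia and 861 at least 2-fold lower. They held 19 of the 30 highest ratios of all probe sets above the floor on both arrays. The highest of them went from 268 to 35668, above the highest named gene, and the lowest went from 9315 to 265, below the lowest named gene.

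In hypoxia, heat shock genes were higher with a median log2 ratio of 4.25. Array scaling of the size that 5 other scalings spanned is argued against as the whole cause, since their lowest median was 3.81. Keeping gene-specific probe sets alone was no test of probe sets shared between similar genes. All 7 members already stood on such probe sets, so the median stayed at 4.25. Whether these probes also bind transcripts of similar genes was not tested. Handling other than oxygen cannot be told apart from the treatment, because the hypoxic cells stood in another vessel at 5.0 times the cell density. Low oxygen, crowding and the vessel remain open, as does binding of the probes to similar transcripts.

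Plastid-encoded transcripts were higher with a median log2 ratio of 0.80. Ratios were above 0 for 67 of 69 genes, so leaving out the 10 highest, which gave 0.74, could hardly have come out otherwise and is no test. Scaling stays open for the absolute direction. The lowest median over 5 other scalings was 0.29, with hybridisation control centring, which is still above 0. It passed the upper end of the random lists in the main setting, 0.28, by less than its spread. That spread was the probe set SD divided by the square root of the number of members. Under hybridisation control centring itself the random lists ended at -0.23. The list stood above all random lists under each scaling. A centring moves the list and its random lists together, however, so this cannot decide the question. A larger share of RNA without stable poly(A) tails in the hypoxia sample is a candidate explanation, since 14 mitochondria-encoded genes had a median of 0.82 and 5S ribosomal RNA was higher too. Nuclear photosynthesis genes, whose transcripts carry such tails, had a median of 1.04, and higher organelle transcript levels in hypoxia remain open as well.

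Ribosome biogenesis factors were lower with a median log2 ratio of -1.49, after a ribosomal protein gene was noticed among the lowest ratios. A chance pick of genes from the bottom of the ranking is argued against. The factors were listed from background knowledge without genes already seen there, and -1.49 lies below the random lists' lower end of -0.49. Random lists draw genes independently, however. With 1 array per group, a chance difference between the samples that moves such genes together cannot be excluded. Array scaling of the size that 5 other scalings spanned is argued against as the whole cause, since their highest median was -0.89. A larger scaling error was not tested. RNA degradation is argued against by the 3′ over 5′ ratios, which differed between the arrays by at most 1.18-fold. No biological explanation was tested, and low oxygen, crowding and the vessel were not separated.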

How the results depend on the processing

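Centring on the hybridisation controls, counting all probe sets, and the plastid list without its highest members were chosen after the data had been seen. No paired analysis was possible because each group has 1 array, and for the same reason leaving out a replicate was not possible. Leaving ADH1 and PDC1 out of the core hypoxia list, and shared genes out of the KIN10 list, removed 0 measured members and so tested nothing.

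The count of genes at least 2-fold higher, 1037, became 2059 with reference gene centring, 528 with hybridisation control centring, 2273 with the floor at the 20th percentile, 632 at the 60th, 1798 at 1.5-fold, 422 at 3-fold, and 2027 over all probe sets. The count lower, 1156, became 352, 2455, 1404, 686, 2227, 350 and 2025 in the same order. Both centrings shift the ratios of genes clear of the floor by a fixed amount, which moves genes across the threshold. The floor limits ratios and sets which genes are measured. Why the reference genes and hybridisation controls differed from the other probe sets was not tested. The counts at other fold thresholds and over all probe sets follow from how many features can pass.

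The core hypoxia median of 2.52 became 3.36 with the floor at the 20th percentile, 1.71 at the 60th and 4.71 with 16 added and no floor, because genes at the floor in control set it. Reference gene centring and hybridisation control centring shift all ratios of genes clear of the floor alike, and ratios near the floor by other amounts. Under them the medians were 0.62 and -0.48 for fermentation, 0.60 and -0.51 for glycolysis, 2.202 and 1.09 for KIN10 genes, 0.87 and -0.24 for branched-chain breakdown, and 1.07 and -0.035 for ATG8 genes. They were 1.64 and 0.53 for nuclear photosynthesis, 4.85 and 3.81 for heat shock, 0.44 and -0.67 for mitochondrial retrograde genes, 0.0 by construction and -1.11 for reference genes, and 1.403 and 0.29 for plastid genes.

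The core hypoxia, heat shock and plastid lists stood at percentile 100 under every alternative run, and the KIN10 list at 99.95 or above. Values as deposited and both centrings move a list and its random lists together. The percentiles could therefore hardly change under them, and they are no test of scaling. The photosynthesis list, at percentile 97.4, ranged from 97.14 to 99.34 over 12 alternatives and lay above the central range in 9, with 97.93 for 10 bins. Both centrings are among the 9, and all reuse the same arrays, so that count adds no support. Of 841 alternative values of single named genes, 645 stayed within the probe set spread, 196 moved beyond it, and 0 called values changed sign. Of the moves, 75 came with reference gene centring and 72 with hybridisation control centring. Their fixed shifts exceed that spread for genes clear of the floor. Values as deposited shift all such genes by less than the spread, and 0 moved. The tally is therefore mostly set by the choice of alternatives and is no measure of stability. Only ratios of at least 2-fold counted as called, and the alternatives could hardly reverse these, so the absence of sign changes is no test. Of 58 named genes at least 2-fold apart, 10 came within 2-fold in at least 1 alternative. Signal near the floor limits the size of a change, which is then a bound.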

Other observations

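The lists described here were drawn up after the ranking of genes had been seen. For the ribosome biogenesis factors the tests by background list and by scaling were written before the list's values were seen, and the other lists here had no test written beforehand.

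Genes of the protein synthesis machinery were lower in hypoxia. Of 98 measured genes for cytosolic ribosomal proteins, 73 were at least 2-fold lower, 0 at least 2-fold higher and 0 above a ratio of 0. The 73 became 25 with reference gene centring and 97 with hybridisation control centring. Their median log2 ratio was -1.32, below all 10000 random lists, and it was -0.72 in the setting least in its favour, centring on the reference genes. AT1G15250 went from 2041 to 324, a ratio of -2.61, AT3G16780 from 8404 to 1443 at -2.50, and AT3G28900 from 7124 to 1392 at -2.31. The ribosomal protein gene AT5G39850, at -3.02 among the lowest ratios, was not in this list. Of 44 measured ribosome biogenesis factors, 37 were at least 2-fold lower and 0 at least 2-fold higher, against 19 lower with reference gene centring and 41 with hybridisation control centring. AT1G52930, a Brix-domain gene of ribosomal RNA processing, went from 5238 to 843, a ratio of -2.59, and AT3G05060 from 4222 to 750.4, a ratio of -2.45. DIM1A, at 0.21, was the 1 factor above 0.

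Genes of endoplasmic reticulum folding and of the proteasome lay mostly below 0, though with reference gene centring the proteasome median was 0.02. Among 4 genes of endoplasmic reticulum folding, AT5G07340 and ATERDJ3B were at least 2-fold lower, at -1.62 and -1.08, CRT1b was at -0.94 and BZIP60 at 0.22. Their median was -1.01 at percentile 1.58, and at 2.59 with no matching on signal. It was -0.41 with reference gene centring, with 1 gene at least 2-fold lower, and -1.51 with hybridisation control centring, with 3 lower. Among 9 proteasome subunit genes, AT5G45620 and AT1G79210 were at least 2-fold lower, both close to the threshold at -1.04 and -1.01, which left 0 lower with reference gene centring and 5 with hybridisation control centring. Their median was -0.59 at percentile 5.22. Among 5 other chaperone genes, which leave out the DnaJ genes and Hop3, Hop2 was at least 2-fold higher, at 1.15, and Hop1 was at -0.93. That median was 0.28 at percentile 72.7, and -0.22 with hybridisation control centring.

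Mitochondria-encoded transcripts were higher for part of the genes measured. Of 14 genes, 7 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.82 at percentile 99.9. With hybridisation control centring the median was 0.32, with 3 higher and 1 lower, and with reference gene centring it was 1.43, with 8 higher. The respiratory chain genes nad6, nad5, cox1 and nad9 were at 2.78, 1.63, 1.62 and 1.48, while nad1 was at -0.55.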
